A study of Rattus norvegicus with 10 samples.

How the data were processed

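Total RNA of cultured neonatal rat ventricular cardiomyocytes was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds 1 log2 value per probe set and array, made with PLIER in Affymetrix Expression Console 1.1, per the submitters' processing notes. The settings of that normalization and the base of the logarithm are not given in the sources used here. Base 2 was taken from the deposited log2 values, whose lowest level on each array, shared by many probe sets, corresponds to 10.0 to 10.97 on the linear scale. Equally ranked values differed by at most 0.263 between arrays, so the deposited log2 values had already been brought to nearly the same distribution, and no further scaling was applied. Between 1990 and 2278 probe sets per array lay at that lowest level, and 946 did so on all 10 arrays, so differences of dim genes can be understated. For arrays, the number of samples limits the precision.

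The table has 31099 probe sets, of which 57 control probe sets were left out. A platform annotation table gave 1 gene symbol to 20832 probe sets, several symbols to 436 and none to 9831, with 14218 different symbols. Symbols were compared with the rat gene table of assembly GRCr8, used for names only, and 0 were updated through the gene identifier. Coordinates are not given, because the array annotation names no genome build. Probe sets in the lowest 25% of mean log2 value over all arrays (below 5.09) were left out, which kept 23281. For genes with more than 1 probe set, the one with the highest mean over all arrays was used, and probe sets with several or no symbols were kept on their own, which gave 18393 tested genes and unnamed probe sets, 11846 of them with 1 symbol.

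Groups came from the treatment given in the sample labels. The titles also give the culture series, numbered 1 to 4 here. The series design speaks of 3 arrays per treatment from separate series of isolation and culture, while the labels give 4 pulsed arrays, all of which were used. Each array held RNA pooled from duplicate experiments, so the spread between arrays is that between culture series. Whether the series pair the arrays was checked on deviations from the group means. Arrays of the same series correlated at 0.347 to 0.640 in all 8 pairs, and arrays of different series and groups at -0.583 to 0.494 in 25 pairs with a median of -0.25. Deviations from a group mean cancel within the group, so positive correlations within series push the others down, and that contrast is partly built in.

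The following choices were made before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, two-sided) on all 10 arrays, with culture series as a fixed block because the groups do not hold the same series. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. In this fit a comparison also draws on the third group, so a fitted change can differ from the differences within series. Shifts of 19 gene lists and 8 marker lists of other cell types were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison. Counts of list members were also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. Of the camera calls, 0 held with an estimated correlation in each of the 3 comparisons, in which 1, 4 and 4 lists had an unadjusted p under 0.05. Fry, which tests whether the genes of a list move on balance one way, called 0, 2 and 3 lists, and its mixed test, for change in either direction, 0, 5 and 10. The 2 fry calls were the fibroblast and antioxidant lists, and the 3 were these and the extracellular matrix list. No called list differed in sign between its median, its mean and its test.

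The genes named were set by rule. These were, per comparison, the 8 largest rises and the 8 largest falls among genes with 1 symbol that passed and moved the same way in every series holding both groups. To these were added the 3 largest passing members of each list, or its member with the largest change where none passed, and Nppa, Nppb, Myh6, Myh7, Acta1, Gja1, Atp2a2 and Ppargc1a in any case. Other list members given as examples were chosen after their values were seen.

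Alternatives covered no block, a random block (duplicateCorrelation, statmod 1.5.0), only the series or groups compared, quantile normalization, median centring, other filters and probe set rules, trended priors, a minimum fold change of 1.5 and leaving out each array. Leaving out each culture series was added after the data were seen. So were the scaling, filter and probe set alternatives and the fits of only the series or groups compared for the lists, and every alternative but separate arrays for the correlation of the changes. Pseudocounts were not needed because the values were already on a log scale.

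The procedure was tested on simulated data with the real means of the 18393 genes and their residual spread as moderated by eBayes, in which 200 genes were changed. At 2-fold, 92.5% of the changed genes were recovered for pulsed against nonpulsed, 94.0% for blebbistatin against pulsed and 88.0% for blebbistatin against nonpulsed, and at 1.5-fold 11.0%, 0.0% and 0.0%. Those simulated genes were independent of each other, unlike real ones, and moderated spreads differ less between genes, so the recovery may be overstated. Figures were drawn with matplotlib 3.10.9.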

Results

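Gene expression was measured on Affymetrix rat arrays in primary cultures of ventricular heart muscle cells from newborn Lewis rats. After a recovery phase the cultures were kept for 3 days without electric stimulation (nonpulsed, n = 3 arrays), with electric pulses (pulsed, n = 4), or with the same pulses and blebbistatin, a myosin II inhibitor that blocks contraction (pulsed with blebbistatin, n = 3). Pulses were given at 1 Hz and 2 V/cm, and blebbistatin at 10 µmol/L. The arrays came from 4 separate series of cell isolation and culture, and each array held RNA pooled from duplicate experiments. Series 1 held a nonpulsed and a pulsed array, series 2 and 3 held all 3 groups, and series 4 held a pulsed array and a pulsed array with blebbistatin. The number of arrays limits the precision of every value. Median log2 values lay between 6.57 and 6.78 over the 10 arrays. Each comparison gives the limma estimate with culture series as a block and its SE, and values quoted per group are means ± SD.

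The comparison of pulsed with nonpulsed cultures addressed the response to electric pacing. Genes of energy metabolism and electrical excitation were higher as groups in pulsed cultures, most of all in series 1, while single genes did not pass the test. All 28 measured members of the fatty acid oxidation list had a positive change, with a median log2 change of 0.34 (camera, adjusted p = 1.7e-08, but adjusted p = 0.697 with an estimated correlation). All 26 glycolysis and glucose genes were also positive, with a median of 0.31 (camera, adjusted p = 4.2e-05, and adjusted p = 0.697 with an estimated correlation). The ion channel and junction list had a median of 0.43 over 23 genes, of which 20 were positive (camera, adjusted p = 1.3e-05, and adjusted p = 0.697 with an estimated correlation). In series 1, 2 and 3 the medians were 0.76, 0.15 and 0.10 for fatty acid oxidation, 0.92, 0.14 and 0.08 for glycolysis and 0.89, 0.29 and 0.14 for ion channels. Of the glycolysis genes, 5 were among 20 genes known to respond to low oxygen, whose median difference was 0.72 in series 1.

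The largest change within each of these lists was that of Kcnip2, which encodes a subunit of the transient outward potassium channel (log2 change 1.59, SE 0.29), Pgam2, the muscle form of phosphoglycerate mutase (1.02, SE 0.29), and Angptl4, an inhibitor of lipoprotein lipase (0.82, SE 0.74). Angptl4 was higher in only 1 of 3 series (differences of -0.06, -0.09 and 1.23). Kcnip2 had a mean log2 value of 6.36 ± 1.85 (SD, n = 3) in nonpulsed and 8.23 ± 1.24 (SD, n = 4) in pulsed arrays, and its difference was positive in all 3 series that held both groups. The potassium channel gene Kcnj11 had a change of 0.91, the glucose transporter gene Slc2a1 of 0.74, and the fatty acid oxidation genes Cpt1b and Hadh of 0.60 and 0.58. Adjusted over the list alone, 1 ion channel gene (Kcnip2) passed, and 0 of the fatty acid oxidation and 0 of the glycolysis genes did in limma.

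Smaller positive shifts by camera were found for the sarcomere list (median 0.23, 20 of 23 positive, adjusted p = 0.00818), oxidative phosphorylation (0.16, 29 of 30, adjusted p = 0.00234), the tricarboxylic acid cycle (0.17, 13 of 14, adjusted p = 0.0434), mitochondrial regulators (0.13, 19 of 21, adjusted p = 0.0249) and muscle atrophy and autophagy (0.18, 13 of 17, adjusted p = 0.0354). Each of these calls was lost at adjusted p = 0.697 with an estimated correlation. In series 3 the medians of the sarcomere (-0.00), tricarboxylic acid cycle (-0.01) and mitochondrial regulator (-0.03) lists were not positive, against 0.74, 0.59 and 0.40 in series 1. Those of oxidative phosphorylation and atrophy were 0.00 and 0.03 in series 3, against 0.50 and 0.45 in series 1. The examples with the largest change were Myom2, a sarcomeric M-band protein (0.89, SE 0.24), Ppargc1b, a coactivator of mitochondrial genes (1.03, SE 0.33), Cox8b (0.44, SE 0.19), Idh2 (0.37, SE 0.14) and Bnip3 (0.64, SE 0.32), which stood apart in the pulsed array of series 1. Calcium handling genes had a median of 0.16 over 21 genes (camera, adjusted p = 0.0924), with Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 0.73 (SE 0.23).

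A further 6 lists had negative shifts by camera. These were cholesterol synthesis (median -0.17, 16 of 17 negative, adjusted p = 6.4e-06), the cell cycle (-0.11, 28 of 30 negative, adjusted p = 0.000147), extracellular matrix (-0.06, 22 of 28 negative, adjusted p = 0.00162), inflammation and interferon (-0.12, 12 of 20 negative, adjusted p = 0.00212), heat shock and unfolded protein response (-0.05, 12 of 19 negative, adjusted p = 0.0314) and actin, SRF and adhesion (-0.07, 18 of 28 negative, adjusted p = 0.0379). With an estimated correlation the inflammation list had an adjusted p = 0.529 and the others an adjusted p = 0.697. The median was positive in series 2 for cholesterol synthesis (0.01) and in series 3 for the cell cycle (0.23), extracellular matrix (0.06) and actin (0.12) lists, and 7 of the 14 lists called in this comparison had the same direction in every series. The member with the largest change in the inflammation list was Ptgs2, the inducible cyclooxygenase, with mean log2 values of 10.21 ± 0.32 (SD, n = 3) in nonpulsed and 9.37 ± 1.89 (SD, n = 4) in pulsed arrays. The Ptgs2 difference was -3.65 in series 1, -0.01 in series 2 and -0.76 in series 3. Cnn1, Chac1, Msmo1, Timp1 and Aurka had changes of -0.53, -0.48, -0.34, -0.33 and -0.31.

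Among the marker lists of other cell types, 0 of 8 passed camera. Fibroblast markers had a median of -0.02, smooth muscle and pericyte markers -0.07, endothelial markers -0.02, macrophage and leukocyte markers 0.03, erythroid markers -0.09, Schwann and neural markers 0.04, mesothelial and epicardial markers 0.08 and atrial markers 0.14. In series 1 alone the fibroblast median was 0.03 and the smooth muscle and pericyte median -0.52. The endothelial gene Pecam1 had a change of 1.03 and was the 1 endothelial gene that passed when adjusted over the list alone. Lists that did not pass included hypertrophy and stretch (-0.05), immediate early genes (-0.10), antioxidant genes (0.05) and targets of the aryl hydrocarbon receptor (-0.11). Their members with the largest change were Gdf15 (-0.70, SE 0.33), Fosl1 (-0.67, SE 1.01, and -3.25, -0.33 and -0.17 in series 1, 2 and 3), Hmox1 (0.66, SE 0.26) and Ahr (-0.30, SE 0.39).

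Genes reported whatever their test had changes of 0.48 for Gja1, the gap junction protein connexin 43 (SE 0.17), 0.39 for Myh6 (SE 0.13) and 0.28 for Myh7 (SE 0.15), the alpha and beta myosin heavy chains, and 0.35 for Atp2a2, the calcium pump of the sarcoplasmic reticulum (SE 0.14). They were 0.50 for Ppargc1a, a coactivator of mitochondrial genes (SE 0.20), 0.14 for Acta1 (SE 0.23), 0.13 for Nppb (SE 0.11) and -0.12 for Nppa (SE 0.12). For Gja1, Myh6, Atp2a2 and Ppargc1a the pulsed array was above its nonpulsed partner in all 3 series. Further probe sets had changes of 0.16, 0.68 and 0.40 for Atp2a2, 0.62 for Myh6, 0.57 for Gja1 and 0.37 for Myh7.

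In limma, 0 of 18393 genes and unnamed probe sets passed the adjusted threshold, and the smallest Benjamini-Hochberg adjusted p was 0.491. At an unadjusted p under 0.05 there were 1674, of which 1440 were higher and 234 lower in pulsed cultures, against 920 that chance gives. Without series 1 there were 885, below that chance value. The count of genes that passed the adjusted threshold stayed 0 in the fits without the block and with a random block. The differences were widest in series 1, where 886 genes differed by more than 2-fold, against 114 in series 2 and 45 in series 3, and without series 1 the number of shifted lists was 5 in place of 14 (9 without the pulsed array of series 2). Without series 1 the fitted medians of the tricarboxylic acid cycle (-0.01), actin (0.10), immediate early (0.40) and cell cycle (0.06) lists changed sign, as did those of the matrix (0.01) and heat shock (0.01) lists without the replicate block.

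**Figure D1:**
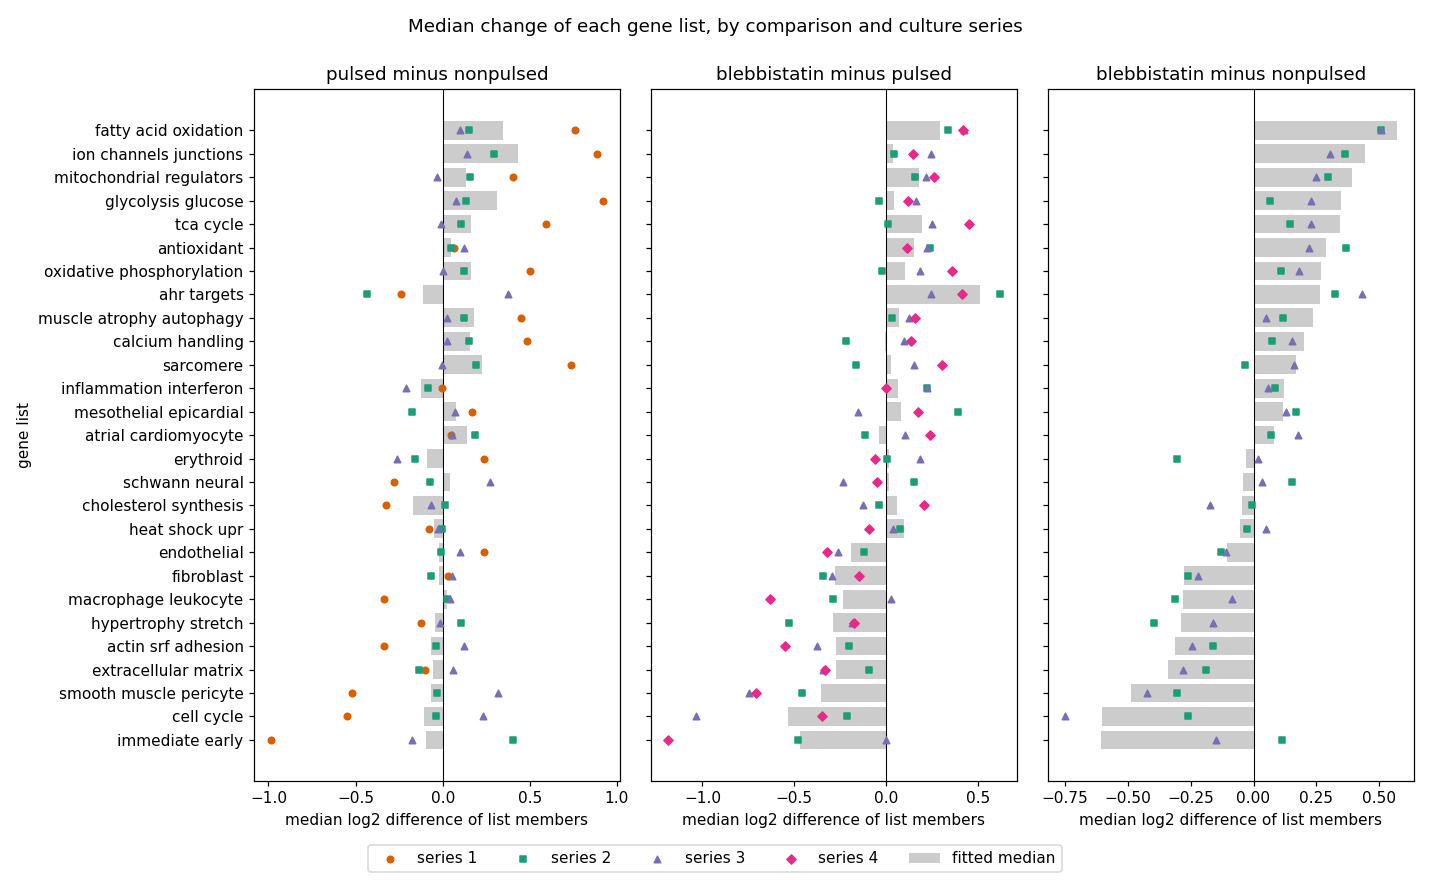
Median log2 difference of the members of each of the 27 gene lists (vertical axis) in the 3 comparisons (panels). Bars give the fitted value over all arrays and points the difference within each culture series that holds both groups. The fatty acid oxidation list lay above 0 in every series of all 3 panels, and its pulsed minus nonpulsed median was 0.76 in series 1, 0.15 in series 2 and 0.10 in series 3.

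The comparison of pulsed cultures with and without blebbistatin addressed what changed when contraction was blocked while pacing went on. No array held a nonpulsed culture with blebbistatin, so an effect of blocked contraction cannot be told apart from other effects of the drug. Nmrk2, which encodes a nicotinamide riboside kinase, rose 3.15-fold (log2 change 1.66, SE 0.11), from a mean log2 value of 6.59 ± 1.07 (SD, n = 4) to 8.52 ± 1.24 (SD, n = 3). Ptgis, the prostacyclin synthase gene, fell 2.81-fold (log2 change -1.49, SE 0.11), from 10.77 ± 0.18 (SD, n = 4) to 9.22 ± 0.25 (SD, n = 3). Clec3b, which encodes tetranectin, fell 2.93-fold (log2 change -1.55, SE 0.13). Lists of cytoskeletal, matrix and cell division genes shifted down by camera, and lists of fatty acid oxidation and antioxidant defence shifted up. With an estimated correlation 0 of 27 lists passed, and the smallest was an adjusted p = 0.178 with an estimated correlation.

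Nmrk2 (probe set 1378423_at, limma, Benjamini-Hochberg adjusted p = 0.0168), Ptgis (probe set 1370012_at, adjusted p = 0.0229) and Clec3b (probe set 1386128_at, adjusted p = 0.0307) were the 3 genes that passed, and each moved the same way in series 2, 3 and 4. The same arrays chose these genes, so that likeness adds no support. A further probe set of Clec3b, 1377452_at, had a change of -0.10. With the mean of its probe sets the call of Clec3b was lost (change -0.82, adjusted p = 0.108). At an unadjusted p under 0.05 there were 2176 genes, of which 1146 were higher and 1030 lower.

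Cell cycle genes had a median log2 change of -0.54, with 29 of 30 negative (camera, adjusted p = 4.0e-12, and adjusted p = 0.426 with an estimated correlation). The examples were Ccna2, which encodes cyclin A2 (-0.82, SE 0.27), Prc1 (-0.80, SE 0.25) and Cdk1 (-0.74, SE 0.28), and 0 of the 30 passed in limma, over all genes or adjusted over the list alone. The median was -0.21 in series 2, -1.03 in series 3 and -0.35 in series 4. The pulsed array of series 3 stood apart on this list, with a median log2 value of 8.89 against 8.41 to 8.47 in the other pulsed arrays.

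Extracellular matrix genes had a median of -0.27, with 26 of 28 negative (camera, adjusted p = 3.7e-11, and adjusted p = 0.286 with an estimated correlation). Their median was -0.09 in series 2, -0.34 in series 3 and -0.33 in series 4. Adjusted over the list alone, 6 of these genes fell, among them Lox, the lysyl oxidase that crosslinks collagen and elastin (-0.95, SE 0.13), Eln, elastin (-0.91, SE 0.18), Loxl1 (-0.70, SE 0.11) and Fn1, fibronectin (-0.43, SE 0.10). Genes of actin, SRF and adhesion had a median of -0.27, with 27 of 28 negative (camera, adjusted p = 3.7e-11, and adjusted p = 0.286 with an estimated correlation). Adjusted over the list alone 9 of these fell, including the smooth muscle type contractile genes Cnn1 (-1.87, SE 0.36), Tagln (-1.05, SE 0.24) and Acta2 (-0.66, SE 0.18) and the actin crosslinker Flna (-0.62, SE 0.19).

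Markers of other cell types moved with these groups. Of these, 4 of the 11 smooth muscle and pericyte markers were also on the actin list and 6 of the 12 fibroblast markers on the matrix list. Smooth muscle and pericyte markers had a median of -0.36 with all 11 negative (camera, adjusted p = 6.9e-07, and adjusted p = 0.353 with an estimated correlation), fibroblast markers -0.28 with 10 of 12 negative (camera, adjusted p = 1.6e-05, and adjusted p = 0.178 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.23 with 10 of 11 negative (camera, adjusted p = 9.6e-05, and adjusted p = 0.353 with an estimated correlation), and endothelial markers -0.19 with 7 of 9 negative (camera, adjusted p = 0.00195, and adjusted p = 0.286 with an estimated correlation). The macrophage and leukocyte median was 0.02 in series 3. Within the fibroblast list Dpt, which encodes dermatopontin, fell when adjusted over the list alone (-1.28, SE 0.14), and Col1a1 was at -0.12 (SE 0.09) and Pdgfra at 0.11 (SE 0.18). Adjusted over the list alone, Lmod1 (-1.47), C1qa (-1.20, with 1 blebbistatin array at the lowest level), Mrc1 (-0.66) and Pecam1 (-0.82) fell in their lists. Mesothelial and epicardial markers had a median of 0.08, atrial markers -0.04, erythroid markers 0.01 and Schwann and neural markers 0.02, and none of these 4 passed camera. The difference between the 3' and 5' beta-actin control probe sets, a sign of RNA quality, had a mean log2 value of 0.59 ± 0.12 (SD, n = 3) in nonpulsed, 0.67 ± 0.05 (SD, n = 4) in pulsed and 0.72 ± 0.04 (SD, n = 3) in blebbistatin arrays, and it was higher with blebbistatin in series 2 and 3 but not in series 4. For GAPDH it was 0.11 ± 0.04 (SD, n = 4) in pulsed and 0.20 ± 0.02 (SD, n = 3) in blebbistatin arrays, higher in all 3 series, and for hexokinase 0.95 ± 0.11 (SD, n = 4) and 0.92 ± 0.11 (SD, n = 3).

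Hypertrophy and stretch genes had a median of -0.29, with 14 of 18 negative (camera, adjusted p = 0.000117, and adjusted p = 0.286 with an estimated correlation). Edn1, the endothelin 1 gene, fell when adjusted over the list alone (-1.13, SE 0.22), and Hbegf was at -1.22 (SE 0.64). Immediate early genes had a median of -0.47, with 18 of 20 negative (camera, adjusted p = 0.000786, and adjusted p = 0.673 with an estimated correlation), and their median was 0.00 in series 3, and 0.09 in the fit without series 4. The example with the largest change was Dusp1, a phosphatase of MAP kinases (-0.87, SE 0.23).

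Fatty acid oxidation genes had a median of 0.29, with 27 of 28 positive (camera, adjusted p = 5.7e-07, and adjusted p = 0.516 with an estimated correlation). Examples were Ucp3 (0.79, SE 0.56, and 2.81, -0.04 and -0.43 in series 2, 3 and 4), Acot2 (0.64, SE 0.17) and Acaa2 (0.55, SE 0.17). Mitochondrial regulators had a median of 0.18, with 20 of 21 positive (camera, adjusted p = 0.000786, and adjusted p = 0.516 with an estimated correlation), and the retinoid receptor gene Rxrg a change of 0.64 (SE 0.24). A further probe set of Rxrg, 1392271_at, had a change of 0.14. The tricarboxylic acid cycle had a median of 0.20, with 13 of 14 positive (camera, adjusted p = 0.0330, and adjusted p = 0.775 with an estimated correlation), and Dlst a change of 0.26 (SE 0.13). Its median was 0.01 in series 2, 0.25 in series 3 and 0.45 in series 4. Oxidative phosphorylation had a median of 0.10 (camera, adjusted p = 0.0530), with Cox7a1 at 0.46 (SE 0.24).

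Antioxidant genes had a median of 0.15, with 17 of 20 positive (camera, adjusted p = 0.000300, and adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone 4 rose, among them Hmox1, heme oxygenase 1 (0.96, SE 0.26), Gclm, a subunit of the enzyme that starts glutathione synthesis (0.64, SE 0.09), and the metallothionein gene Mt2A (0.99, SE 0.18). In series 4 Hmox1 hardly differed, with log2 values of 10.09 in the pulsed and 10.13 in the blebbistatin array. Targets of the aryl hydrocarbon receptor had a median of 0.51 over 7 genes (camera, adjusted p = 0.0418, and adjusted p = 0.426 with an estimated correlation), with Aldh3a1 at 0.92 (SE 0.28) and Cyp1a1 at 0.70 (SE 0.27). The heat shock and unfolded protein response list did not shift (median 0.10, camera, adjusted p = 0.692), yet adjusted over the list alone 3 members rose and 4 fell. Those that rose included the stress transcription factor gene Ddit3 (0.82, SE 0.16) and Trib3 (0.69, SE 0.12), and those that fell included the endoplasmic reticulum chaperone genes Pdia4 (-0.55, SE 0.10) and Hsp90b1 (-0.48, SE 0.09).

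The sarcomere list had a median of 0.03 and did not pass (camera, adjusted p = 0.779), nor did calcium handling (median -0.00, adjusted p = 0.426), ion channels and junctions (0.04, adjusted p = 0.537), glycolysis (0.04, adjusted p = 0.779), muscle atrophy and autophagy (0.07, adjusted p = 0.242), cholesterol synthesis (0.06, adjusted p = 0.261) or inflammation and interferon (0.07, adjusted p = 0.311). Members of these lists with the largest change were Myl7, an atrial myosin light chain (0.71, SE 0.22), Aldoc (-0.87, SE 0.42), Trim54 (0.40, SE 0.13), Mvd (0.48, SE 0.14) and the calcium-binding protein gene Casq1, with mean log2 values of 9.76 ± 0.79 (SD, n = 4) in pulsed and 7.86 ± 0.53 (SD, n = 3) in blebbistatin arrays. Adjusted over the list alone, Kcnip2 (1.32, SE 0.29) and the channel subunit gene Kcne1 (1.47, SE 0.30), which was high in all 3 arrays of series 3, rose and the T-type calcium channel gene Cacna1g (-1.02, SE 0.24) fell, and the interferon-stimulated gene Isg15 (1.37, SE 0.22) rose. Myh7 had a change of -0.49 (SE 0.15), Nppb -0.33 (SE 0.11), Nppa -0.22 (SE 0.12), Ppargc1a 0.30 (SE 0.20), Myh6 0.08 (SE 0.13), Acta1 0.03 (SE 0.23), Gja1 -0.04 (SE 0.17) and Atp2a2 -0.00 (SE 0.14), and none of these passed. Gja1 was 0.05 to 0.09 and Atp2a2 0.03 to 0.11 higher with blebbistatin within each series, and the fitted values also draw on the nonpulsed arrays. Further probe sets had changes of 0.26, 0.18 and 0.27 for Atp2a2, 0.52 for Myh6, -0.02 for Gja1 and -0.79 for Myh7.

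The count of 3 genes was 1 without the replicate block, 0 with only the series that held both groups, and 30 when series 1 was left out. It was 0 without series 2 or without series 3, and 1 without series 4.

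The comparison of pulsed cultures with blebbistatin against nonpulsed cultures gave the net difference of both treatments. The largest rises were those of Kcnip2, which was 7.54-fold higher (log2 change 2.91, SE 0.33), Doc2g (2.30, SE 0.24), Nmrk2 (2.12, SE 0.12) and Tmem179 (2.06, SE 0.28). Further rises were those of Osgin1, an oxidative stress-induced gene (1.79, SE 0.15), Aqp7, a glycerol channel (1.78, SE 0.18), Adss1, an enzyme of the purine nucleotide cycle in muscle (1.53, SE 0.19), and Plin5, a coat protein of lipid droplets (1.52, SE 0.21). The largest falls were those of Cemip, which binds and degrades hyaluronan and was 5.73-fold lower (log2 change -2.52, SE 0.32), Prss3bl1 (-2.10, SE 0.23), Mfap5, a microfibril protein (-2.08, SE 0.19), and Col15a1, a basement membrane collagen (-1.75, SE 0.21). Mamdc2 (-1.73, SE 0.20), Mrgprf (-1.72, SE 0.21), Ptgis (-1.60, SE 0.13) and the P-cadherin gene Cdh3 (-1.56, SE 0.20) also fell. The size for Mamdc2 may be understated, because 1 blebbistatin array lay at the lowest level.

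In limma, 63 genes and unnamed probe sets passed, 36 higher and 27 lower, with fold changes between 1.60 and 7.54. Of these, 20 of the higher and 22 of the lower had a gene symbol. The adjusted p was 0.00672 for Nmrk2, 0.0319 for Kcnip2, 0.0311 for Aqp7 and Mfap5, 0.0357 for Cemip and 0.0305 for Osgin1 and Ptgis. All 63 moved the same way in series 2 and 3, the series that held both groups, which adds no support because the same arrays chose them. The 3 genes of the blebbistatin against pulsed comparison were among the 63. For Kcnip2 the mean log2 value was 6.36 ± 1.85 (SD, n = 3) in nonpulsed, 8.23 ± 1.24 (SD, n = 4) in pulsed and 10.17 ± 0.45 (SD, n = 3) in blebbistatin arrays. A further probe set of Kcnip2, 1368639_at, had a change of -0.10 and another, 1370773_a_at, of 3.27.

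**Figure D2:**
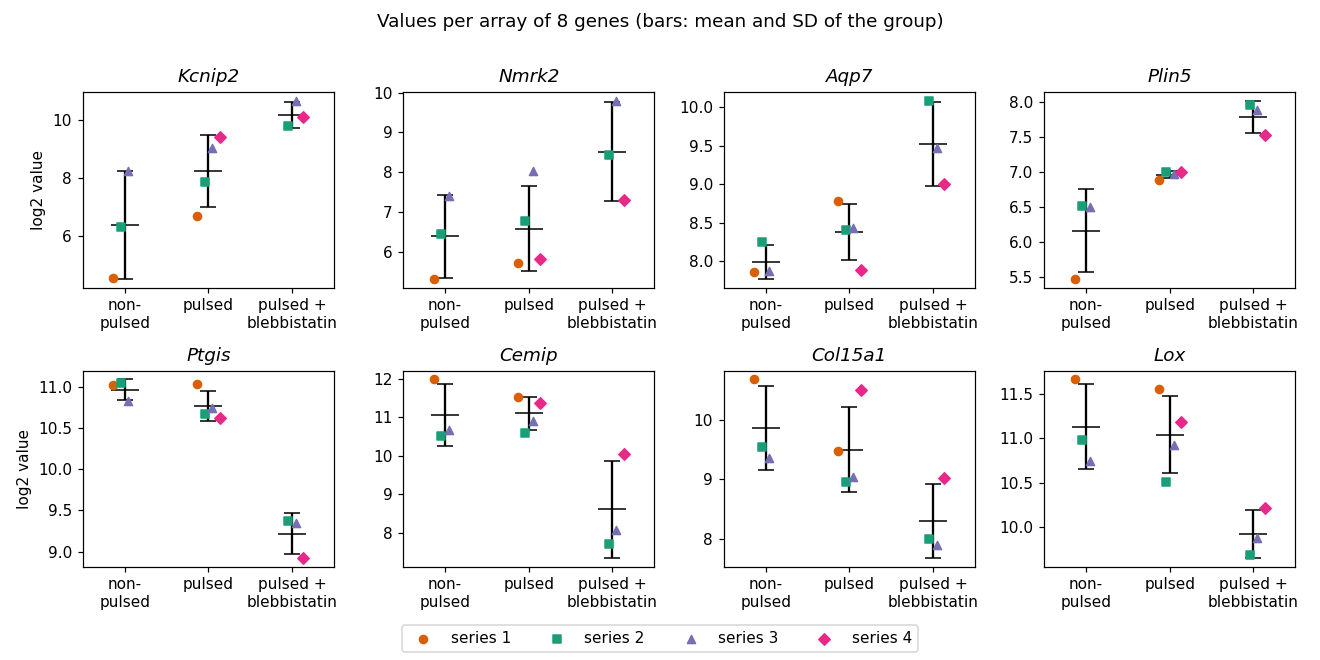
Log2 values (vertical axis) of 8 genes that passed in the comparison of pulsed cultures with blebbistatin against nonpulsed cultures, for each array by group (horizontal axis). Points are arrays, coloured by culture series, and black bars give the group mean and SD. Ptgis had means of 10.97, 10.77 and 9.22 in the nonpulsed, pulsed and blebbistatin groups.

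Fatty acid oxidation genes had a median change of 0.57 with all 28 positive (camera, adjusted p = 1.2e-10, and adjusted p = 0.387 with an estimated correlation). In limma 0 of the 28 passed over all genes and 25 rose when adjusted over the list alone, among them Acot2 (1.21, SE 0.19), Hadh (1.08, SE 0.16), Acaa2 (1.02, SE 0.19) and Cpt1b, the mitochondrial carnitine palmitoyltransferase of muscle (1.01, SE 0.19). Of 21 mitochondrial regulators (median 0.39, camera, adjusted p = 0.000299, and adjusted p = 0.556 with an estimated correlation), 7 rose when adjusted over the list alone, including Ppargc1b (1.52, SE 0.37), Rxrg (1.44, SE 0.27), Ppargc1a (0.80, SE 0.22) and Esrra (0.57, SE 0.13). A further probe set of Rxrg, 1392271_at, had a change of 0.33. The tricarboxylic acid cycle (median 0.34, Idh3b 0.53), oxidative phosphorylation (0.27, Cox8b 0.78) and glycolysis (0.35, Pgam2 1.83) shifted up by camera, at adjusted p = 0.00460, 0.000597 and 0.00485. Each of these calls was lost at adjusted p = 0.626 with an estimated correlation. Within series 2 and 3 their medians were smaller than fitted, at 0.14 and 0.23, 0.11 and 0.18, and 0.06 and 0.23.

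Ion channels and junctions had a median of 0.44 (camera, adjusted p = 0.000927, and adjusted p = 0.556 with an estimated correlation), and 1 of 23, Kcnip2, passed over all genes and 6 when adjusted over the list alone, including Kcnj11 (1.17, SE 0.33) and Kcnd3 (0.95, SE 0.18). Antioxidant genes had a median of 0.29 (camera, adjusted p = 0.0185, and adjusted p = 0.329 with an estimated correlation). Gclm rose over all genes (0.68, SE 0.10, limma adjusted p = 0.0496), and 6 rose when adjusted over the list alone, including Hmox1 (1.62, SE 0.30) and Mt2A (1.02, SE 0.21). Muscle atrophy and autophagy genes had a median of 0.24 (0.12 and 0.05 in series 2 and 3; camera, adjusted p = 0.0301, and adjusted p = 0.574 with an estimated correlation), with Trim54 at 0.94 (SE 0.15) and the ubiquitin ligase gene Fbxo32 at 0.77 (SE 0.23) among 4 that rose when adjusted over the list alone.

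Cell cycle genes had a median of -0.60 with all 30 negative (camera, adjusted p = 2.8e-13, and adjusted p = 0.387 with an estimated correlation), and 6 fell when adjusted over the list alone, including Prc1 (-1.03, SE 0.29) and Mcm6, a subunit of the replicative helicase (-0.83, SE 0.19). Extracellular matrix genes had a median of -0.34 with 27 of 28 negative (camera, adjusted p = 7.7e-12, and adjusted p = 0.329 with an estimated correlation). Lox fell over all genes (limma, -1.08, SE 0.14, 2.12-fold lower) and 7 fell when adjusted over the list alone. Actin, SRF and adhesion genes had a median of -0.31 (camera, adjusted p = 1.1e-09, and adjusted p = 0.387 with an estimated correlation), with 8 lower when adjusted over the list alone, including Cnn1 (-2.40, SE 0.41). Within series 2 and 3 the medians were -0.26 and -0.75 for cell cycle, -0.19 and -0.28 for matrix and -0.16 and -0.25 for actin genes. Hypertrophy and stretch (-0.29), immediate early (-0.61) and cholesterol synthesis (-0.05, and 0.0014 without the replicate block) genes also shifted down by camera, at adjusted p = 0.000129, 0.000242 and 0.0484. With an estimated correlation these had an adjusted p = 0.329, an adjusted p = 0.600 and an adjusted p = 0.626. The immediate early median was 0.11 in series 2 and -0.15 in series 3, so the fitted value was seen in neither series that held both groups. The members with the largest change were Hbegf (-1.77, SE 0.72, and -0.68 and -0.96 in series 2 and 3), Fosl1 (-1.49, SE 1.14, and 0.14 and -0.10 in series 2 and 3) and Acat2 (-0.34, SE 0.20).

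Beside these groups, smooth muscle and pericyte markers had a median of -0.49, macrophage and leukocyte markers -0.28 and fibroblast markers -0.28, at camera adjusted p = 7.0e-06, 0.000583 and 3.0e-05. With an estimated correlation they had an adjusted p = 0.387, an adjusted p = 0.387 and an adjusted p = 0.243. Endothelial (-0.10), erythroid (-0.03), Schwann and neural (-0.04), mesothelial and epicardial (0.12) and atrial (0.08) markers did not pass. The lists of sarcomere (0.17), calcium handling (0.20), heat shock and unfolded protein response (-0.05), inflammation and interferon (0.12) and aryl hydrocarbon receptor target (0.26) genes did not pass either. Their members with the largest change were Myl7 (mean log2 values of 10.31 ± 0.67 in nonpulsed and 11.07 ± 0.57 in blebbistatin arrays), Casq1 (-2.47, SE 0.58), Ddit3 (0.79, SE 0.18), Ptgs2 (-2.28, SE 1.03, and -0.72 and -1.08 in series 2 and 3) and Cyp1a1 (0.99, SE 0.30). Myh6 was at 0.47 (SE 0.15), Gja1 at 0.44 (SE 0.19), Atp2a2 at 0.35 (SE 0.16), Nppa at -0.34 (SE 0.14), Myh7 at -0.21 (SE 0.17), Nppb at -0.20 (SE 0.12) and Acta1 at 0.17 (SE 0.26), and none of these passed. Further probe sets had changes of 0.42, 0.86 and 0.665 for Atp2a2, 1.14 for Myh6, 0.54 for Gja1 and -0.42 for Myh7.

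The count of 63 was 30 without the replicate block, 1020 with a random block, 2 with only the series that held both groups and 1 without the filter on dim probe sets. It was 0 without series 2 or without series 3 and 8 without series 4, and 6 and 1 without only the pulsed array of series 2 and of series 3.

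Whether the changes with pulsing and with blebbistatin ran in the same or in opposite directions was examined across genes, which are not independent replicates. The log2 changes had a Pearson correlation of 0.19 and a covariance of 0.0093 over 18393 genes and unnamed probe sets. Because both comparisons use the pulsed arrays with opposite sign, 200 simulations of unchanged groups gave a mean correlation of -0.36, between -0.39 and -0.34, and a mean covariance of -0.0086. The observed covariance was 0.0179 above the simulated mean. The simulated genes were independent of each other, unlike real ones, so the range of the simulations is too narrow for real genes. With separate arrays for the 2 changes the correlation was 0.52 (pulsing from series 1 and 2, blebbistatin from series 3 and 4) and 0.36 (pulsing from series 1 and 3, blebbistatin from series 2 and 4). At an unadjusted p under 0.05, 190 genes were higher with both, where 89.7 would be shared by independent lists, and 39 were lower with both, where 13.1 would be shared. In opposite directions, 60 were higher with pulsing and lower with blebbistatin, against 80.6, and 24 lower with pulsing and higher with blebbistatin, against 14.6, and part of these overlaps may come from the shared pulsed arrays. The correlation was -0.08 without series 1 and -0.02 without series 4, where simulations of unchanged groups gave a mean of -0.43 in both. It was 0.10 and 0.0044 without the pulsed array of series 2 and of series 3 (simulated mean -0.50 in both). It was 0.30 without the nonpulsed array of series 3 (simulated mean -0.24).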

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

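Of the tests in this part, those of array scaling and RNA quality in series 1 and of the relation on single pairs and nonpulsed arrays were set before their results were seen, and the others were chosen after.

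In the pulsed group of 4 arrays, 1 array stood far from the other 3 for 4 genes and 1 list. The gap to the nearest array, as a share of the group's range, was 0.871 for Bnip3 (11.81 in series 1, against 10.47 to 10.64), 0.875 for Aldoc (9.76 in series 1, against 7.57 to 7.84), 0.900 for Kcne1 (7.99 in series 3, where the other 2 arrays were also high, against 3.79 to 4.21), 0.845 for Tmem179 (6.57 in series 2, against 7.35 to 7.50) and 0.876 for the median of the cell cycle list (8.89 in series 3, against 8.41 to 8.47). Chance alone puts about 1 in 20 groups past the limit used here. Of 95 items examined (genes, lists and the median value of the array), 5 were past it, about the share that chance alone gives.

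Differences between pulsed and nonpulsed arrays were widest in series 1. Fewer heart muscle cells in the nonpulsed culture of series 1 could move the markers of all other cell types alike. Fibroblast and smooth muscle or pericyte markers moved apart instead (medians 0.03 and -0.52, permutation p = 0.00119 over 12 and 11 genes). That p treats genes as independent, though the smooth muscle and pericyte list had an estimated correlation of 0.60. Other cell types need not shift alike, so the values speak at most against an equal shift. Fewer heart muscle cells stays open, and the sarcomere median was 0.74 higher in the pulsed array of series 1. For Myh6 the nonpulsed array of series 1 stood low, at 12.57 against 13.18 and 13.19 in the other nonpulsed arrays. Gja1 (11.77 against 12.69 and 12.81) and Atp2a2 (12.53 against 13.10 and 13.20) were also low in that array. Nppa differed less (13.56 against 13.69 and 13.71). The pulsed array of series 1 had a Myh6 value of 13.38, against 13.33 to 13.43 in the other pulsed arrays. Remaining differences in array scale were small, and quantile normalization, which removes them, left the SD over genes in series 1 nearly the same. The SD went from 0.452 to 0.456, then 1.66 times the larger of those of series 2 and 3. The deposited values had already been brought to nearly the same distribution, so the test could hardly move the SD. It therefore cannot decide on scaling of the arrays, and an effect of the earlier scaling stays open. RNA quality stays open, since the 3' to 5' difference was largest in series 1 for 1 of 3 control genes. A response to pacing that differed between cultures may also account for the pattern and was not tested apart from these.

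With blebbistatin, lists of stromal, contractile and cell division genes shifted down by camera, calls that were all lost with an estimated correlation (adjusted p = 0.178 to 0.426). By fry the fibroblast list passed (adjusted p = 0.0189), while the matrix, actin and cell cycle lists did not (fry, adjusted p = 0.0695, 0.140 and 0.221). Whether an equally lower share of every other cell type is the whole cause stays open. The fibroblast and smooth muscle or pericyte medians, averaged within series, were -0.28 and -0.44 (permutation p = 0.0317). In the fit over all arrays they were closer, at -0.28 and -0.36. The permutation treats genes as independent, though the smooth muscle and pericyte list had an estimated correlation of 0.60, so it cannot decide this. Fewer cells of a single type, or fewer of several types to different degrees, could still contribute, as endothelial and macrophage medians were also negative (-0.19 and -0.29). Remaining differences in array scale were removed by quantile normalization. It left the medians of the matrix, actin and cell cycle lists, relative to all genes, at 0.933 or more of their size. The deposited values already had nearly the same distribution, so this test could hardly move the medians and cannot decide on scaling of the arrays. An effect of the earlier scaling of the deposited values stays open. An effect of blebbistatin on expression within cells stays open and was not tested.

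The fitted changes with pulsing and with blebbistatin correlated positively across genes, which not every pair of series shows. In simulations with independent genes, unlike real ones, the shared pulsed arrays gave a negative covariance, and the observed value was 0.0179 above the simulated mean. On average they therefore do not produce the positive correlation, but its spread by chance among real genes was not tested. Whether series 1 and 4 alone carry it stays open, as the correlations on separate arrays without them were 0.164 and 0.083, while those with series 1 or 4 were 0.043, 0.416 and 0.539 (pulsing in series 1 with blebbistatin in series 2, 3 and 4), 0.161 and -0.037 (pulsing in series 2 and 3 with blebbistatin in series 4). An axis on which arrays differ whatever the treatment may contribute, since nonpulsed series 2 minus series 1 correlated at 0.39 with the blebbistatin change of series 3 and 4, and nonpulsed series 3 minus series 1 at 0.41 with that of series 2 and 4. The latter was 1.01 times the correlation of the series 1 pulsing change (0.40), while the former was below its counterpart (0.56), and all 4 values share the nonpulsed array of series 1.

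Other ways of splitting the same arrays into groups of the same sizes were fitted in the same way. For pulsed against nonpulsed, 12 of 35 splits gave at least the real 14 lists (highest other 18), so chance is not excluded for the lists. All 35 of 35 gave at least the real count of 0 genes (highest other 3), as any split must, so the splits say nothing on that count. For blebbistatin against pulsed, 3 of 35 gave at least 3 genes and 11 of 35 at least 14 lists (highest other 29 and 17), so chance is not excluded there either. The split with 29 genes is the real grouping with only the pulsed array of series 1 moved to the blebbistatin arrays, and leaving out series 1 gave 30 genes. So many calls point to a structure of the samples, here the place of that array, which was not tested. For blebbistatin against nonpulsed, 1 of 10 splits, the real one, gave 63 genes and 17 lists (highest other 0 and 16), and 10 splits are too few for a share under 0.05. Among splits that part as many series pairs as the real one, 4 of 8 gave at least 14 lists for pulsed against nonpulsed, 2 of 8 for blebbistatin against pulsed, and 1 of 4 at least 17 for blebbistatin against nonpulsed.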

How the results depend on the processing

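Leaving out each culture series, for the lists the scaling, filter, probe set and group or series alternatives, and for the correlation all but separate arrays were chosen after the data were seen. For pulsed against nonpulsed the count of genes was 0 in limma under every alternative. For blebbistatin against pulsed (3 genes) it was 1 without the replicate block, 7 with a random replicate block, 0 with only the groups or only the series compared, 0 without the filter, 6 with probe sets below the median level left out, 2 with the mean of probe sets, 8 with a trended prior and 4 with a robust one. Leaving out 1 array gave 0 to 30 (30 without either series 1 array, 0 without any series 2 array, the pulsed or the blebbistatin array of series 3, 1 without either series 4 array); leaving out whole series 1 to 4 gave 30, 0, 0 and 1. For blebbistatin against nonpulsed (63 genes) it was 30 without the replicate block, 1020 with a random replicate block, 2 with only the groups or only the series compared, 1 without the filter, 110 with all probe sets, 163 with a trended and 136 with a robust prior. Leaving out 1 array gave 0 to 46 (0 without the nonpulsed or the blebbistatin array of series 2 or the blebbistatin array of series 3, 6 and 1 without the pulsed array of series 2 and 3, 7 without the nonpulsed array of series 3, 8 without either series 4 array); leaving out series 2, 3 or 4 gave 0, 0 and 8. Leaving out arrays leaves fewer for the fit, yet 1 count rose to 30 without series 1, and the cause was not tested for any setting. Shifted lists numbered 14, 14 and 17. With an estimated correlation there were 0 in each, with fry 0, 2 and 3, and with its mixed test 0, 5 and 10. They numbered 11 in blebbistatin against nonpulsed with only the groups or series compared, and 5 in pulsed against nonpulsed without series 1; leaving out 1 array gave 5 to 17, 12 to 15 and 14 to 17. Without the replicate block the lists numbered 13, 14 and 16. The correlation of the changes (0.191) was -0.0792 without series 1, -0.0205 without series 4, 0.515 and 0.362 on separate arrays, and -0.0792 to 0.302 without 1 array, and each value with series or arrays left out lay above its 200 simulations of unchanged groups. Those simulated genes were independent of each other, so lying above them does not show a relation beyond chance. List medians turned sign, the cause not being tested, in pulsed against nonpulsed without series 1 (tricarboxylic acid cycle -0.0135, actin, SRF and adhesion 0.105, immediate early 0.395, cell cycle 0.0552), where leaving out 1 array gave -0.0135 to 0.248, -0.126 to 0.105, -0.399 to 0.395 and -0.323 to 0.0552. The actin list also did so without the pulsed array of series 2 (0.0039). They also did so there without the replicate block (extracellular matrix 0.0097, heat shock 0.0137), with probe sets below the median level left out (macrophage and leukocyte -0.0254) and without the filter (Schwann and neural -0.131). In blebbistatin against pulsed they did so without series 4 (sarcomere -0.101, without 1 array -0.101 to 0.135; immediate early 0.0861, without 1 array -0.658 to 0.0861), and in blebbistatin against nonpulsed without the replicate block (cholesterol synthesis 0.0014). Of the named genes that passed, 0 turned sign under these alternatives. Counted over named genes and alternatives, calls were lost in 45 cases and gained in 7 for blebbistatin against pulsed, and lost in 266 and gained in 61 for blebbistatin against nonpulsed.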

Other observations

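The tests in this part were all chosen after the results were seen.

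Genes for aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA, were higher as a family with blebbistatin than in pulsed cultures without it. Of 32 measured, 31 had a positive change, with a median of 0.21 (fry, Benjamini-Hochberg adjusted p = 0.000714 over 4 families), and 3 passed when adjusted over the family alone. The median was 0.23 in series 2, 0.15 in series 3 and 0.23 in series 4, at percentiles 100, 99.8 and 99.7 of 10000 random gene sets of like level, so high in 3 of 3 series. Mitochondrial ribosome genes had a median of 0.15, with 70 of 73 positive, but a fry adjusted p = 0.238. Their median was high among random sets in 2 of 3 series, at 0.00 (percentile 60.2) in series 2, 0.23 (percentile 100) in series 3 and 0.42 (percentile 100) in series 4. Cytosolic ribosome genes had a median of -0.02 (0.02 under quantile normalization) and proteasome genes of 0.06, with fry adjusted p = 0.518 and 0.218. A concerted rise of the tRNA synthetase genes with blebbistatin is a hypothesis found and tested on the same arrays.

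Genes known to respond to low oxygen had their highest median in the pulsed array of series 1, the array in which Bnip3 and Aldoc stood apart. Of 20 further hypoxia genes, 18 were higher in that array than in its nonpulsed partner, with a median log2 difference of 0.72, against 0.12 in series 2 and 0.05 in series 3. The median lay at percentile 100 of 10000 random gene sets of like level in series 1, 95.5 in series 2 and 89.1 in series 3, so a smaller rise in the other series is not excluded. Examples were Egln3 (1.88), Pdk1 (1.54), Vegfa (1.33) and Slc2a1 (1.12). The median log2 value of these genes was 10.06 in that array, 9.10 in its nonpulsed partner, and 9.41 to 9.75 in the other pulsed arrays. Single genes differed, with Slc2a1 at 10.13 in the pulsed array of series 1 and 10.24 in that of series 4. Other lists rose as much in series 1, such as sarcomere (0.74), fatty acid oxidation (0.76), ion channels (0.89) and glycolysis (0.92). Others fell, such as the cell cycle list (-0.55). The percentile among random genes therefore cannot single out low oxygen. Lower oxygen in the pulsed culture of series 1 remains a candidate for part of the wide differences there but was not tested. The arrays cannot separate a higher oxygen use from handling. Of the 20 genes, 5 also belong to the glycolysis list.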
